A study of Mus musculus with 7 samples.

How the data were processed

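Islets of 7 pregnant mice were profiled on day 15 of pregnancy, 3 of them PrlR+/+ and 4 PrlR+/-. Per the labels, females were mated at 12 to 16 weeks of age, the islets of each mouse were processed separately, and 250 ng of total RNA with an RNA integrity number above 8.5 was labelled with biotin for each array. The authors deposited a table of log2 values with 2 decimals, 1 column per mouse, ranging from 1.73 to 13.97. The log2 scale was read from the values. Per the submitters' processing notes the software was Affymetrix Expression Console 1.2.0.20; the background correction, normalization and summarization are not given in the sources used here. No array scanner files, scan dates or batches were analysed here, so batch was not tested. Groups were taken from the source labels. The sample codes in the labels differ in form between the genotypes, and what they stand for is not given.

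The probe sets were named with the platform annotation of the array. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed with a gene. Entrez identifiers of 21698 of the first kind were found in a RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols and served to find neighbouring genes. Probe sets with no or several symbols were left out of the tests. For 999 genes with more than 1 probe set, the probe set with the highest mean over the 7 arrays stood for the gene, which left 19938 genes. No filter on dim genes and no further normalization was applied. Arrays have no read depth, and no signal above background was given, so values near the floor may not reflect transcript levels. Probe sets of the targeted gene were not analysed here, and neither were 3 of 18 genes chosen by name.

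Differences are PrlR+/- minus PrlR+/+ on the log2 scale, from limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 2-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error of a single gene is limma's moderated one. That of the prolactin-responsive list comes from an unmoderated fit on the list means per mouse. Tables were joined with pandas 2.3.3 in Python 3.11.15. Adjusted p values of gene lists come from limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 26 lists with at least 4 measured genes. camera with an estimated correlation and fry were run beside it; with either, 0 lists were called. Exact permutation tests of a list mean used all 35 splits of the 7 mice into 3 and 4, with a smallest p of 0.0286; over all lists the smallest permutation p after adjustment was 0.386. The limma steps were tested on simulated data: 20 runs of 19938 genes with 200 genes changed recovered 55.7% of 1.5-fold, 84.9% of 2-fold and 98.3% of 4-fold changes, with 4.39% of calls false, and a list lowered by 0.3 was called in 20 of 20 runs. The simulated genes varied independently of each other, unlike the real ones. The 200 changed genes of a run were spread over these sizes of change, and fewer changed genes were not tried.

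The main tests and the rule for named genes were fixed before the data were examined. So were the 27 gene lists, with 468 entries of which 426 were measured. They were prolactin-responsive islet genes, JAK-STAT signalling and feedback, serotonin synthesis and signalling, cell cycle and proliferation, G1 cyclins, kinases and inhibitors, beta cell identity, glucose sensing and insulin secretion, markers of alpha, delta, PP, acinar, duct, endothelial, myeloid, lymphocyte, stellate, Schwann and neuron, red blood and adipocyte cells, unfolded protein response, apoptosis and survival, dissociation and stress response, interferon response and antigen presentation, oxidative phosphorylation, cholesterol synthesis, genes disallowed in beta cells, and genes beside the targeted locus. For 5 lists the mean, the median and camera's direction differed in sign: cell cycle, alpha cell, duct, unfolded protein response and genes beside the locus. The named genes are the targeted gene, genes past the threshold with groups that do not overlap or, where fewer than 5 pass, the 8 genes per direction of smallest unadjusted p whose groups do not overlap, without clone or model names; of each list, members that pass or the 2 of smallest unadjusted p; and 18 genes chosen by name. Other members of the prolactin-responsive list were named after their values were seen.

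Alternatives were other variance models of eBayes, array weights, quantile normalization or median centring, filters on dim genes (the 40th percentile of the mean, or values above the median of all probe sets in at least 3 samples), the mean of all probe sets of a gene, the acinar marker mean as a covariate, the replicate number as a block, leaving out each mouse, other thresholds, the other set tests and a distance of 10 Mb. Added after the data were seen were the first principal component of the unnamed probe sets as a covariate, the prolactin-responsive list without Lrrc55, and a focus on the fit without PrlR+/+ 3. The tests of the beta cell share, of the acinar markers and of the unnamed probe sets as explanations were also chosen then.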

Results

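Transcripts were measured in pancreatic islets of female mice on day 15 of pregnancy, with an Affymetrix expression array for each mouse. The islets came from 3 mice with an intact prolactin receptor gene (PrlR+/+) and 4 mice heterozygous for a null allele of it (PrlR+/-), on the C57BL/6 strain background. The prolactin receptor binds prolactin and placental lactogens and signals through the kinase Jak2 and STAT proteins, and it is known to take part in the growth and secretory adaptation of beta cells in pregnancy. The deposited log2 values covered 35556 probe sets and gave 19938 genes for testing. The number of arrays, 3 against 4, limits the precision, and the median standard error of a log2 difference was 0.0977. Across genes, which are not independent replicates, pairs of arrays correlated at r between 0.9883 and 0.9974. The median gene value lay between 7.34 and 7.37 on every array. The spread was narrowest in PrlR+/- 4, with quartiles of 5.82 and 8.97, and widest in PrlR+/- 3, with 5.62 and 9.07. Probe sets unnamed here varied more, with medians of 5.95 in PrlR+/+ 1, 5.92 in PrlR+/+ 3 and 5.94 in PrlR+/- 2, against 5.64 to 5.78 on the 4 other arrays. The targeted gene was not analysed here, so the genotype labels were not checked against its level.

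The comparison of PrlR+/- with PrlR+/+ islets asked which islet transcripts depend on an intact pair of receptor alleles in pregnancy. Genes known to rise in mouse islets in pregnancy or under prolactin or placental lactogen fell as a list in PrlR+/- islets. All 16 measured members had lower means, with a mean log2 difference of -0.50 and a median of -0.453 (camera, adjusted p = 8.67e-13 with the preset correlation). This call was lost with other set tests: adjusted p = 0.275 with an estimated correlation and adjusted p = 0.193 by fry. Lrrc55, an auxiliary subunit of large-conductance potassium channels (probe set 10484503), had a log2 value of 9.38 ± 0.11 (SD, n = 4) in PrlR+/- against 10.17 ± 0.25 (SD, n = 3) in PrlR+/+ islets. Its difference was -0.79 ± 0.12 (SE), and every PrlR+/- mouse lay below every PrlR+/+ mouse. Tph1, the enzyme that starts serotonin synthesis (probe set 10563570), averaged 9.70 ± 1.40 (SD, n = 4) in PrlR+/- and 11.23 ± 0.51 (SD, n = 3) in PrlR+/+ islets, a ratio of 0.346. Its value in PrlR+/- 3 was 7.64, and without that mouse the log2 difference was -0.843 in place of -1.53.

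Among the other members, Cish and Socs2, feedback inhibitors of cytokine receptor signalling induced by STAT5, had log2 differences of -0.46 ± 0.15 and -0.28 ± 0.09 (SE). The groups did not overlap for Socs2, for Tnfrsf11b, which encodes the decoy receptor osteoprotegerin (-0.71 ± 0.23), for Ehhadh of peroxisomal fatty acid oxidation (-0.63 ± 0.21) and for Ivd of leucine breakdown (-0.45 ± 0.12). The tight-junction gene Cldn8 was at -1.17 ± 0.48 and Tph2, a second tryptophan hydroxylase, at -0.62 ± 0.23, while Chgb, Hepacam2 and Fkbp11 lay between -0.05 and -0.01. Of the 16 genes, 9 had an unadjusted p under 0.05 by limma, 0 passed over all genes, and 1, Lrrc55, passed adjusted over the list alone (adjusted p = 0.00483). Lrrc55 was put on the list with knowledge of work on this receptor that may rest on these samples. Its place is therefore not independent evidence of the direction. Without Lrrc55, a setting added after the values were seen, the mean difference of the list was -0.48 (camera, preset correlation, adjusted p = 1.45e-10). The set tests in which the full list lost its call were not run without Lrrc55. The list mean per mouse was 10.69, 10.35 and 10.63 in PrlR+/+ 1 to 3 and 10.36, 10.16, 9.75 and 9.98 in PrlR+/- 1 to 4, so PrlR+/- 1 lay above PrlR+/+ 2. The 2-sided exact permutation test of these means gave p = 0.0857, where the smallest possible p was 0.0286.

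**Figure D1:**
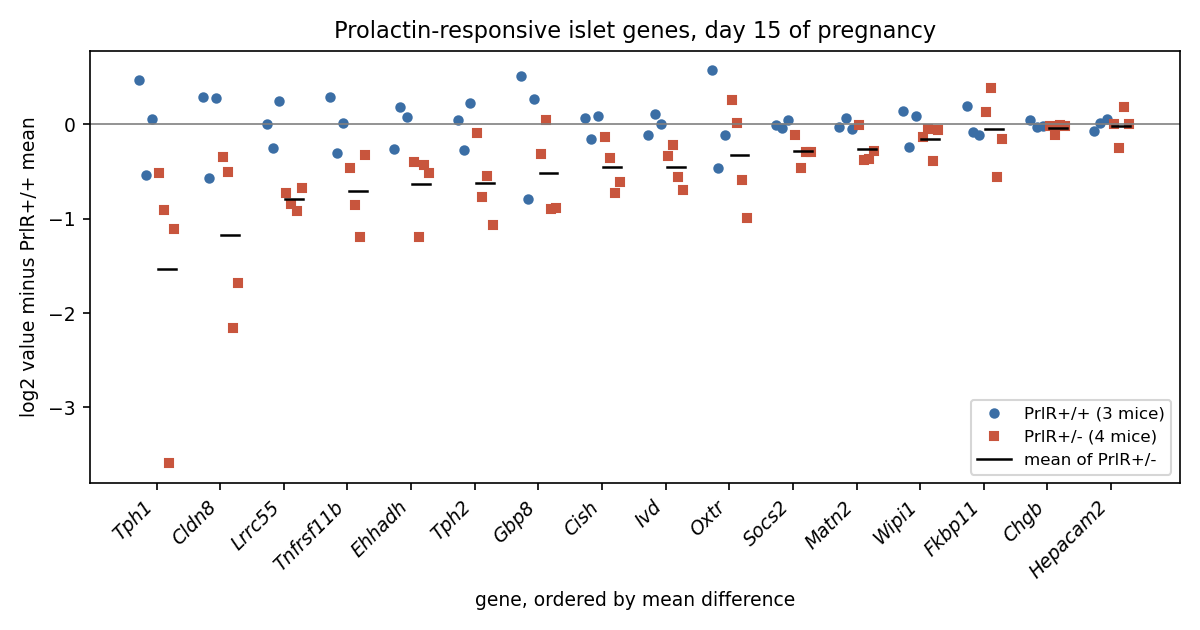
Log2 value of each of the 16 prolactin-responsive islet genes in each mouse, minus the PrlR+/+ mean of that gene, for 3 PrlR+/+ (circles) and 4 PrlR+/- mice (squares), with a bar at the PrlR+/- mean. All 16 bars lie below 0, and the lowest square is Tph1 in PrlR+/- 3.

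No single gene passed in the test over all 19938 genes. limma called 0 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.99, and 438 genes had an unadjusted p under 0.05 (213 higher and 225 lower in PrlR+/-), where chance gives 997. The groups did not overlap for 446 genes, or 2.24%. Chance gives 5.71% only for values without ties, and here up to 4351 probe sets had equal values on 2 arrays. Over all 35 splits of the mice into groups of these sizes, the share ranged from 0.988% to 11.5%. Over the same splits, 203 to 3133 genes had an unadjusted p under 0.05 by limma. Both genotype values lay inside these ranges, so neither was unusually low. Simulated data took the mean and spread of each gene from these arrays, but the genes varied independently of each other. In them the same test recovered 55.7% of 1.5-fold and 84.9% of 2-fold changes. Each run changed 200 genes, spread over 1.5-, 2- and 4-fold. With fewer changed genes the adjustment is stricter and recovery lower, which was not simulated. The 0 calls therefore do not exclude a small number of changed genes. Of the genes tested, 89.9% had a 95% interval of the difference within 1.5-fold in both directions. This share includes dim genes and genes near the top of the measured range, where a difference in transcripts may be hidden.

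None of the following genes passed; they had the smallest unadjusted p among genes whose groups did not overlap. On the higher side in PrlR+/- islets, Lyz2, a lysozyme of macrophages, was at 8.70 ± 0.14 (SD, n = 4) against 8.06 ± 0.13 (SD, n = 3), and the peptide transporter gene Slc15a2 at 7.03 ± 0.55 against 5.64 ± 0.43. Smaller positive differences were measured for Ctla2b (0.54 ± 0.11, SE), Thy1 (0.34 ± 0.09), a surface glycoprotein of T cells, neurons and fibroblasts, the leukocyte integrin gene Itgad (0.33 ± 0.09), Ramp2 of the adrenomedullin receptor (0.32 ± 0.08), D5Ertd615e (0.32 ± 0.08) and the neuronal calcium sensor gene Hpcal4 (0.26 ± 0.07). On the lower side, Fbxw24, an F-box gene, was at 4.76 ± 0.28 (SD, n = 4) against 6.34 ± 0.60 (SD, n = 3), and Sftpd, which encodes surfactant protein D, at 7.09 ± 0.29 against 8.14 ± 0.23. Tmem255a (-0.60 ± 0.15, SE), the adhesion receptor gene Adgrd1 (-0.58 ± 0.14), Pamr1 (-0.42 ± 0.10), the vesicular monoamine transporter gene Slc18a1 (-0.42 ± 0.10) and Lhfpl4 (-0.27 ± 0.07) completed the lower side with Lrrc55. Lyz2, Ctla2b and Fbxw24 have close relatives in the mouse genome whose transcripts the same probes may also bind, so their values are uncertain as to the gene.

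Serotonin genes and the signalling chain below the receptor were not called as lists. Of 14 genes of serotonin synthesis and signalling, 8 had lower and 6 higher means, with a median of -0.0817 (camera, adjusted p = 0.107); the lowest differences were those of Tph1, Tph2 and Slc18a1, and Tph1 and Tph2 are also on the prolactin-responsive list. Serotonin receptor and reuptake genes lay between -0.09 and 0.12. For 22 genes of JAK-STAT signalling and feedback the median was -0.0362 (adjusted p = 0.113), with Jak2 at -0.19 ± 0.10 and the STAT-induced kinase gene Pim1 at -0.15 ± 0.08 (SE). The mean of the 14 serotonin genes was -0.195 with all arrays. The serotonin list was called with either filter on dim genes (-0.284 and -0.328, adjusted p = 0.0416 and 0.0188) and without PrlR+/- 1 (-0.266, adjusted p = 0.0247). These were 3 of 18 alternatives, with adjusted p up to 0.615 for the list. With array weights the mean of the serotonin list was -0.105 and without PrlR+/- 4 -0.149. The JAK-STAT list, with a mean of -0.0509, was called in 2 of 18 alternatives with adjusted p up to 0.52: without PrlR+/- 3 (-0.0706, adjusted p = 0.0387) and with a covariate from the unnamed probe sets added after the data were seen (-0.102, adjusted p = 0.00896). Its mean was smaller without PrlR+/- 2 (-0.0258) and without PrlR+/+ 2 (-0.00466).

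Proliferation genes were not called as a list, and the direction of the list turned with the mouse left out. The median difference of 29 genes of S phase and mitosis was 0.00667 and their mean -0.00672 (camera, adjusted p = 0.759), with a spread of the list mean between mice of 0.235 (SD, n = 3) in PrlR+/+ and 0.23 (SD, n = 4) in PrlR+/- islets. The mean difference was 0.111 without PrlR+/+ 1 (adjusted p = 0.0438), 0.0871 without PrlR+/- 4 (adjusted p = 0.0289) and -0.124 without PrlR+/+ 2 (adjusted p = 0.0147), and over 18 alternatives the list was called higher in 4 and lower in 1, with adjusted p from 0.000895 to 0.946. Mki67, a marker of cycling cells, averaged 7.95 ± 0.47 in PrlR+/- and 7.93 ± 0.50 in PrlR+/+ islets, and the mitotic regulator Foxm1 6.97 ± 0.25 and 6.85 ± 0.25. Pcna was at 0.18 ± 0.11 and the kinesin gene Cenpe at -0.15 ± 0.10 (SE). Of 17 G1 cyclins, kinases and inhibitors the median was -0.025 (adjusted p = 0.489), with Ccnd2, the main D cyclin of beta cells, at -0.07 ± 0.06, Ccnd3 at -0.22 ± 0.15 and Men1, which encodes menin, a restraint on beta cell growth, at 0.18 ± 0.12 (SE).

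Genes of beta cell identity were not called as a list, and none of the 19 passed singly. Their median difference was -0.0233 and their quartiles -0.0979 and 0.0504 (camera, adjusted p = 0.499). Without PrlR+/+ 2 the list was called lower, at a mean of -0.0705 in place of -0.0122 (adjusted p = 0.0219), in 1 of 18 alternatives with adjusted p up to 0.876. Without PrlR+/+ 3 the mean was 0.0297. Ins2, an insulin gene, was at 13.29 ± 0.04 (SD, n = 4) against 13.31 ± 0.04 (SD, n = 3), near the top of the measured range of 1.73 to 13.97, while the transcription factor genes Foxa2 and Nkx6-1 differed by 0.22 ± 0.11 and 0.11 ± 0.06 (SE). Across 17 genes of glucose sensing and insulin secretion the median was -0.0675 (adjusted p = 0.266). The glucose transporter gene Slc2a2 was at 11.90 ± 0.41 against 12.24 ± 0.13. Without PrlR+/- 4, where it was at 11.31, its difference was -0.143 in place of -0.339, and the mean of the list -0.0139 in place of -0.0635. The calcium channel gene Cacna1c differed by 0.17 ± 0.07 and the exocytosis gene Stx1a by 0.12 ± 0.07.

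**Figure D2:**
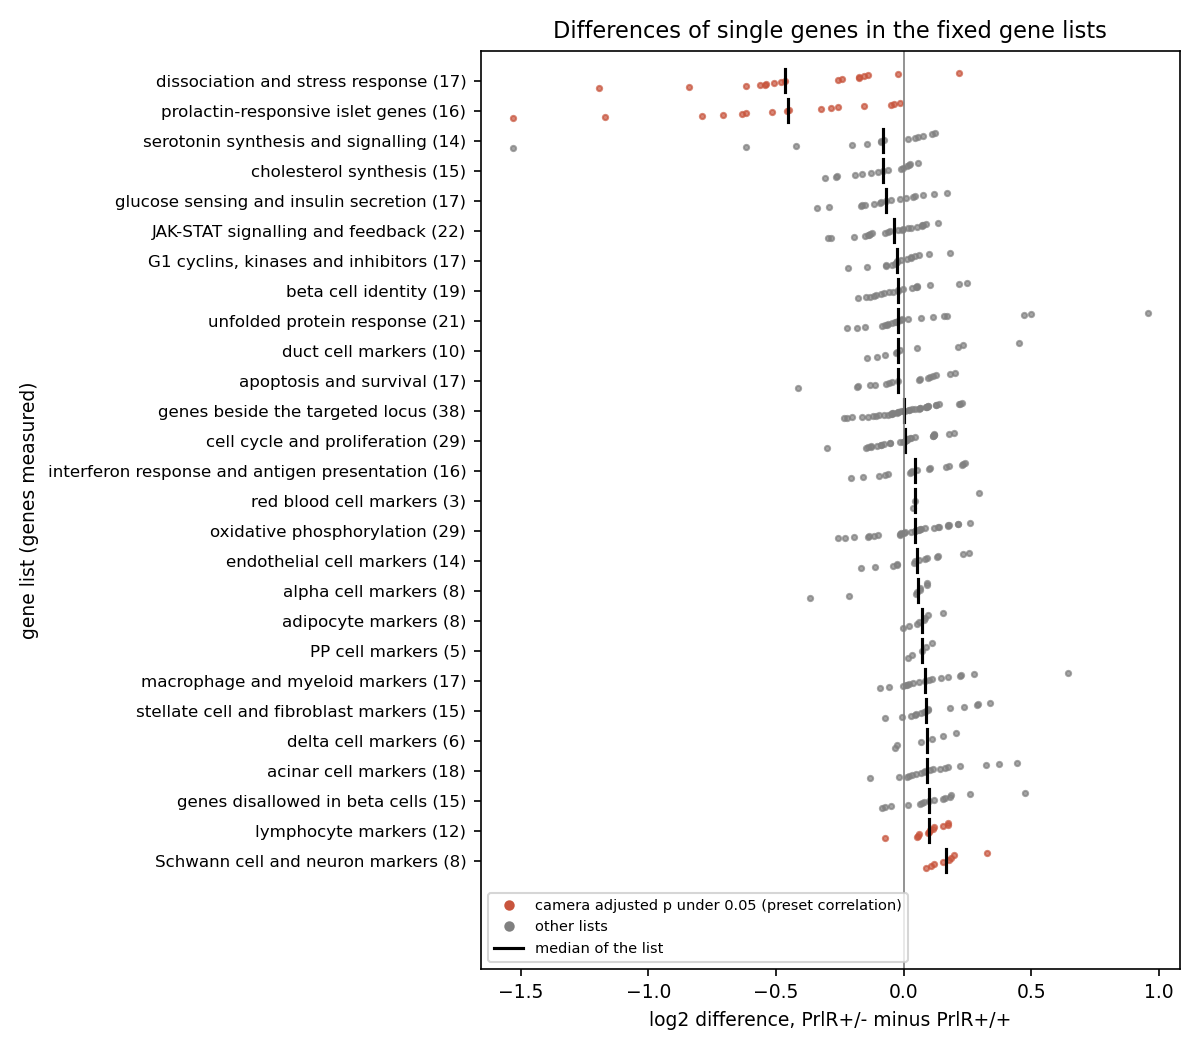
Log2 difference, PrlR+/- minus PrlR+/+, of every measured member (points) of the 27 fixed gene lists, with the number of genes measured in brackets and a bar at each median. Red marks the 4 lists called by camera with the preset correlation, 0 of which were called with an estimated correlation; the medians of the prolactin-responsive list and of the dissociation and stress list lie at -0.453 and -0.464.

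Markers of the other islet endocrine cells were not called as lists. The medians were 0.0583 for 8 alpha cell markers (adjusted p = 0.592), 0.0904 for 6 delta cell markers (adjusted p = 0.619, and called higher in 2 of 18 alternatives with adjusted p from 0.0292 to 0.971, while the mean of 0.0806 was -0.0342 without PrlR+/+ 2) and 0.0742 for 5 PP cell markers (adjusted p = 0.238). All 5 PP cell markers had higher means. Their list mean lay between 9.94 and 9.998 in PrlR+/- and between 9.874 and 9.936 in PrlR+/+ mice. The 2-sided exact permutation test of it gave p = 0.0286, the smallest possible, and 0.386 after adjustment over the lists. The hormone genes Gcg, Sst and Ppy differed by 0.05 ± 0.06, 0.07 ± 0.09 and 0.03 ± 0.06 (SE), and all 3 lay near the top of the measured range. Of the other named members, Gria3 and Irx2 of alpha cells differed by -0.37 ± 0.21 (-0.145 without PrlR+/+ 2) and 0.09 ± 0.07, Rbp4 and Neurog3 of the delta list by 0.16 ± 0.14 and 0.21 ± 0.25, and Aqp3 and Vsig1 of PP cells by 0.11 ± 0.07 and 0.09 ± 0.08.

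Nerve and lymphocyte markers were called slightly higher as lists in PrlR+/- islets with the preset correlation. All 8 Schwann cell and neuron markers had higher means, with a median of 0.166 (camera, adjusted p = 0.00164; adjusted p = 0.275 with an estimated correlation), among them Uchl1 (0.18 ± 0.08, SE) and Nefm (0.18 ± 0.09). Their mean lay between 7.24 and 7.37 in PrlR+/- and between 7.02 and 7.22 in PrlR+/+ mice (2-sided exact permutation test, p = 0.0286, the smallest possible, and 0.386 after adjustment over the lists). Of 12 lymphocyte markers 11 had higher means, with a median of 0.101 (adjusted p = 0.0314; adjusted p = 0.607 with an estimated correlation). Cd3d, a part of the T cell receptor complex, was at 0.18 ± 0.07 and the immunoglobulin gene Ighm at 0.17 ± 0.07. The lymphocyte mean was 6.073 in PrlR+/- 4 and between 5.801 and 5.835 in the 3 other PrlR+/- mice. These levels lie near the lower quartile of genes. That quartile was 5.82 in PrlR+/- 4 and 5.62 to 5.73 on the other arrays, so dim genes lay higher on that array. Without PrlR+/- 4 the mean difference was 0.03 in place of 0.0946 and the call was lost (adjusted p = 0.242). It was also lost without PrlR+/+ 1, PrlR+/+ 2 or PrlR+/- 2, and with quantile normalization (0.0683, adjusted p = 0.0604).

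Exocrine, vascular, myeloid and stromal markers were not called as lists, but 4 of these lists were called higher under several of the 18 alternatives and had smaller means or changed sign with another mouse left out. Acinar markers had a median of 0.0929, with 16 of 18 members higher (adjusted p = 0.113); Cpa1, a pancreatic carboxypeptidase gene, was at 13.68 ± 0.07 (SD, n = 4) and 13.67 ± 0.06 (SD, n = 3), near the top of the measured range, where a difference may be hidden. Try4 differed by 0.44 ± 0.21 and Cela2a by 0.14 ± 0.12 (SE). For 10 duct markers the median was -0.0208 (adjusted p = 0.984), with Sox9 at 0.21 ± 0.12 and Muc1 at 0.45 ± 0.34, which were 0.10 and 0.14 without PrlR+/- 2. Endothelial markers had a median of 0.0533 over 14 genes (adjusted p = 0.266), with Emcn at 0.26 ± 0.09 and Cdh5 at 0.23 ± 0.10. Of 17 macrophage and myeloid markers 14 had higher means, with a median of 0.085 (adjusted p = 0.124). Lyz2 was the 1 member that passed adjusted over the list alone (adjusted p = 0.00495), and Lyz1 was at 0.28 ± 0.14. Stellate cell and fibroblast markers had a median of 0.0867 over 15 genes (adjusted p = 0.0708), with Thy1 as above and Postn at 0.29 ± 0.17. The stellate list was called in 11 of 18 alternatives (adjusted p from 0.000323 to 0.887), among them both scalings and the fits without PrlR+/+ 1, PrlR+/+ 2, PrlR+/- 3 or PrlR+/- 4. Its mean of 0.121 was, however, 0.0347 without PrlR+/- 2 and 0.0627 without PrlR+/+ 3. The acinar list was called in 8 (adjusted p from 7.49e-07 to 0.99), with a mean of 0.268 in place of 0.125 without PrlR+/+ 2, and also without PrlR+/- 1 or PrlR+/- 4. In contrast, its mean was 0.0191 without PrlR+/- 2 and 0.0239 without PrlR+/+ 3. The alternative with the acinar covariate sets the mean of this list to 0 by construction. The myeloid list was called in 7 (adjusted p from 1.36e-06 to 0.696), with a mean of 0.214 in place of 0.116 without PrlR+/+ 1, and also without PrlR+/+ 3 or PrlR+/- 4, whereas without PrlR+/+ 2 its mean was -0.0379. The endothelial list was called in 4 (adjusted p from 0.00896 to 0.781), with means of 0.0931 without PrlR+/- 1 and 0.0826 without PrlR+/- 4 in place of 0.0505. Its positive mean rested on PrlR+/- 2, whose list mean was 9.592 against 9.199 to 9.307 in the other mice. Without that mouse the mean difference was -0.0379. For 3 red blood cell markers, too few for the test, the median was 0.0458, with Epb42 at 0.29 ± 0.14 and Alas2 at 0.04 ± 0.09, and for 8 adipocyte markers it was 0.0713 (adjusted p = 0.238), with Adipoq at 0.15 ± 0.11 and Retn at 0.10 ± 0.08.

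Early response genes, which rise when tissue is handled, fell as a list in PrlR+/- islets, and this rested on 1 PrlR+/+ mouse. Of 17 genes of the dissociation and stress list 16 had lower means, with a median of -0.464 (camera, adjusted p = 0.000107; adjusted p = 0.607 with an estimated correlation). Nr4a1 was at -0.54 ± 0.24 and Junb at -0.48 ± 0.24 (SE). The list mean was 9.54 in PrlR+/+ 3, against 8.20 and 8.52 in PrlR+/+ 1 and 2 and 8.23 to 8.47 in the PrlR+/- mice. Without PrlR+/+ 3 the mean difference was -0.000147 in place of -0.394 (adjusted p = 0.876). In the same fit that of the prolactin-responsive list was -0.463 (camera, preset correlation, adjusted p = 4.18e-10). With all arrays and an estimated correlation, the prolactin-responsive list was not called (adjusted p = 0.275).

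**Figure D3:**
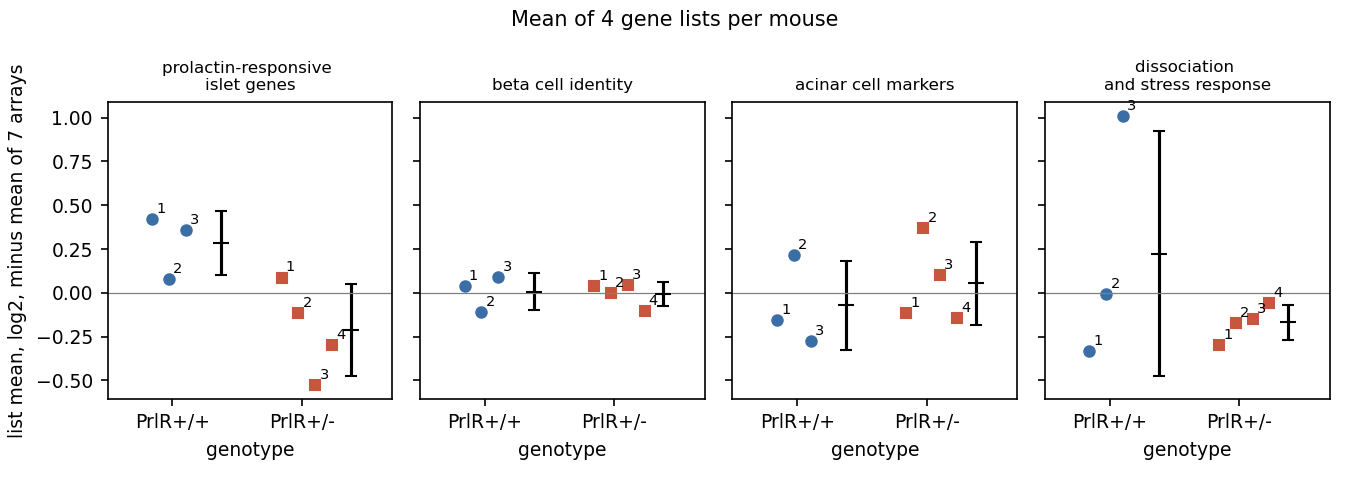
Mean log2 value of 4 gene lists in each mouse, minus the mean over the 7 arrays, for PrlR+/+ (circles) and PrlR+/- (squares), with replicate numbers and, beside each group, its mean and SD. PrlR+/+ 3 stands at 1.01 for the dissociation and stress list, and for the prolactin-responsive list PrlR+/- 1 (0.087) lies above PrlR+/+ 2 (0.0776).

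Genes beside the targeted locus were compared with the rest, since a targeted allele can carry linked alleles of the embryonic stem cell strain. Of 76 genes starting within 20 Mb of the locus on chromosome 15, 0 had an unadjusted p under 0.05, against 438 of 19862 other genes or 2.21% (2-sided Fisher's exact test, p = 0.418). The median absolute log2 difference was 0.0671 beside the locus and 0.0692 elsewhere. For the 38 genes of the fixed list the median difference was 0.00292 (camera, adjusted p = 0.759). Its mean of 0.00419 was smaller than the shift that other scalings gave to all genes (medians of -0.00988 and -0.01), so its sign depends on the scaling. Sub1 and Nup155 had the smallest unadjusted p of that list, with differences of 0.22 ± 0.12 and -0.23 ± 0.13 (SE).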

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

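A PrlR+/- mouse stood apart from the 3 others in 11 of 105 genes and list means checked, where chance gives about 5.25. PrlR+/- 4 accounts for most of these. In it Men1 was at 10.46 against 10.12 in the others, Stx1a at 8.0 against 7.86, Cd3d at 5.13 against 4.96, Sub1 at 11.65 against 11.28 to 11.30, and Cenpe at 5.35 against 5.51. Its lymphocyte marker mean was 6.073 against 5.801 to 5.835, and its red blood cell marker mean 6.243 against 5.907 to 5.95. In PrlR+/- 2 the duct genes Sox9 and Muc1 were at 8.20 and 10.12 against 7.73 to 7.76 and 8.73 to 8.95, and the oxidative phosphorylation mean was 10.21 against 10.31 to 10.33. Ccnd2 was at 12.74 in PrlR+/- 3 against 12.84 to 12.85. The values carry 2 decimals, and 3 equal values make any gap stand out.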

How the results depend on the processing

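The covariate from the unnamed probe sets and the prolactin-responsive list without Lrrc55 were chosen after the data were seen. No gene was called under any planned or added fit at an adjusted p under 0.05, or with all 7 arrays and no covariate at 0.1; 30 genes passed an unadjusted p under 0.05 with a 1.5-fold change. The prolactin-responsive list kept its direction and its call in 19 of 21 alternatives, with means from -0.604 to -0.38 and adjusted p from 1.01e-13 to 0.275; it lost the call with an estimated correlation and with fry, at an unchanged mean of -0.50, and so did the Schwann list (0.169), the dissociation list (-0.394) and the lymphocyte list (0.0946), which left 0 lists in either test. By construction these 2 tests allow for correlated genes. The 19 kept calls all used the preset correlation of 0.01, while the estimate for the prolactin-responsive list was 0.235. The alternatives overlap, since the replicate block gives the same mean differences as leaving out PrlR+/- 4. Of the 22 lists not called, 11 were called under at least 1 alternative. In place of 4 lists, 8 were called with either dim filter, where the lymphocyte list had too few genes, 9 with the covariate, and 4 to 9 with a mouse left out; the cause was not tested. The lymphocyte list lost its call with array weights (0.0457), quantile normalization (0.0683), the mean of all probe sets (0.0909) and the covariate (0.057), and ranged from 0.03 to 0.121 with a mouse left out. The dissociation list ranged from -0.672 to -0.000147, the latter without PrlR+/+ 3. With the replicate block 0 genes and 10 lists were called, the prolactin-responsive mean was -0.472 and the lymphocyte mean 0.03. Same-numbered mice correlated at 0.09, -0.386 and -0.029 in their deviations from the group means, and not every mouse correlated best with its own number. Such correlations also carry the structure of the arrays and cannot decide whether the numbers pair the mice. The labels do not say whether they do. For 41 of the 78 named genes, leaving out 1 mouse made the difference smaller by more than 1.5 times or changed its sign. Of 1374 values of named genes under alternatives 13 changed sign and 0 passed. With array weights these were Sst (-0.00858), Ppy (-0.0127) and Alas2 (-0.000296), with the covariate Alas2 (-0.0217), and with the acinar covariate Cpa1 (-0.0215). Cpa1 is a member of the list whose mean is the acinar covariate, so that fit takes out part of its difference by construction. With a mouse left out they were Sst (-0.035 to 0.13), Cpa1 (-0.0167 to 0.0475), Alas2 (-0.0233 to 0.08), Mki67 (-0.245 to 0.25) and Neurog3 (-0.055 to 0.363). The cause of the other sign changes was not tested. Within 10 Mb of the targeted locus, 0 of 60 genes had an unadjusted p under 0.05. Alternatives for the targeted gene were not run. Signal over background was not known, so dim genes may be limited by the array.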

Other observations

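Lists of the unfolded protein response, apoptosis, interferon response, oxidative phosphorylation and cholesterol synthesis were not called between the genotypes. The median difference was -0.0208 for 21 genes of the unfolded protein response (camera, adjusted p = 0.663), with the stress-induced pseudokinase gene Trib3 at 0.47 ± 0.29 and Creld2 at 0.16 ± 0.10 (SE). It was -0.02 for 17 genes of apoptosis and survival (adjusted p = 0.672), with the death-promoting Bbc3 at 0.20 ± 0.07 and the survival gene Mcl1 at -0.18 ± 0.09. Interferon response and antigen presentation genes had a median of 0.0433 over 16 genes (adjusted p = 0.458), with B2m at 0.18 ± 0.08 and Gbp3 at 0.17 ± 0.09. The mean of this list, 0.0503, ranged from -0.0277 to 0.11 over 18 alternatives, 0 of which called it. Oxidative phosphorylation genes had a median of 0.0458 over 29 genes (adjusted p = 0.672), with Sdha at -0.23 ± 0.12 and Cox7b at 0.17 ± 0.09. Of 15 cholesterol synthesis genes 11 had lower means, with a median of -0.08 (adjusted p = 0.107), Idi1 at -0.31 ± 0.20 and Dhcr7 at -0.26 ± 0.19. The cholesterol list was called lower in 4 of 18 alternatives (adjusted p from 0.00364 to 0.978): with the acinar covariate (-0.142) and without PrlR+/+ 3 (-0.157), PrlR+/- 1 (-0.138) or PrlR+/- 2 (-0.138), in place of a mean of -0.0963, which was -0.0443 without PrlR+/+ 2 and -0.028 without PrlR+/- 4, and changed sign with array weights (0.0215).

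Of 15 genes that mature beta cells keep low, 12 had higher means in PrlR+/- islets, with a median of 0.0983 (camera, adjusted p = 0.107). Arhgdib, a gene abundantly expressed in blood cells, was at 7.88 ± 0.22 (SD, n = 4) against 7.41 ± 0.21 (SD, n = 3), with groups that did not overlap, and the lactate dehydrogenase gene Ldha at 0.26 ± 0.15 (SE). Neither passed over all genes. The list was called higher in 6 of 18 alternatives (adjusted p from 0.00362 to 0.524), among them both filters on dim genes, array weights and the fits without PrlR+/+ 2 (0.168 in place of a mean of 0.111) or PrlR+/- 4 (0.116); the mean was 0.0692 with the acinar covariate and 0.072 without PrlR+/- 2.

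Of the tests that follow, those of the beta cell share, of the acinar markers, of the unnamed probe sets and of the covariate from unnamed probe sets were chosen after the data were seen. The 0 genes called leave nothing to set against chance: all 35 splits of the 7 mice into 3 and 4 gave as many, with 0 in the highest other split. The 4 called lists do not exclude chance either, since 31 of the 35 splits called as many and the highest other split called 10.

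The lower values of prolactin-responsive genes in PrlR+/- islets are the pattern closest to the design. A lower share of beta cells as the whole cause is argued against, since the lower quartile of the beta cell identity list, -0.0979, lay above the median of the prolactin-responsive list, -0.453. Without PrlR+/+ 2, where the identity list was called lower, the means were -0.0705 and -0.604. A lower share as part of the cause was not tested. Of the 19 identity genes, 12 had lower and 7 higher means, and those near the top of the measured range, such as Ins2, may hide a fall. Chance is not excluded: 3 of the 35 splits gave a mean difference as large as -0.50, the highest other being 0.55 for PrlR+/- 2, 3 and 4 against the rest. Camera's unadjusted p with the preset correlation was smallest in the real split (3.33e-14), then in that other split (1.48e-13). This order does not weigh against chance, since the preset of 0.01 lay below the estimate of 0.235 for this list. Array structure as the whole cause is not excluded. With the covariate from unnamed probe sets this list was at -0.38 ± 0.16 in place of -0.50 ± 0.18 (SE of an unmoderated fit on the list means per mouse). It stayed called by camera (adjusted p = 1.04e-07), but only the preset correlation was run with the covariate. The list moved about as much as those that moved most, the myeloid one from 0.116 to 0.253 and the cell cycle one from -0.00672 to 0.117. The covariate is 1 component with 51.6% of the variance of unnamed probe sets. Structure outside it, such as any that follows genotype, is not covered. Whether array structure makes up part of the difference cannot be told apart from genotype, since the 76% kept met the bound of 75%, set before this fit was run, by less than its error. A reduced response to lactogens with 1 intact allele may also account for the pattern and stays open as a hypothesis. It was not tested here, since the targeted gene was not analysed and every mouse was pregnant. Without mice that were not pregnant, it cannot be told apart from a genotype difference already present before pregnancy.

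In the unnamed probe sets, the arrays of PrlR+/+ 1, PrlR+/+ 3 and PrlR+/- 2 stood apart from the 4 others across genotypes. Over genes this was less clear. On the first principal component of the genes PrlR+/- 1 (5.466) lay on the side of these 3 arrays (11.85 to 14.36). The remaining arrays lay at -28.48 to -7.261. Parting these 3 arrays from the 4 others gave 2520 genes with an unadjusted p under 0.05 (limma). The count was 438 by genotype and 3133 with PrlR+/+ 2, PrlR+/- 3 and PrlR+/- 4 apart. Parting these 3 arrays also gave 1086 unnamed probe sets with an adjusted p under 0.05 (limma). These counts restate what was seen, since the arrays were singled out by correlations over the same probe sets. Exocrine tissue carried over with the islets is argued against, since the acinar marker mean spanned 0.645 within these 3 arrays, lowest in PrlR+/+ 3 and highest in PrlR+/- 2 of all 7. A difference in array processing or labelling stays open: 23.2% of unnamed probe sets parted these 3 arrays from the others, against 11.1% of genes, but this share restates what was seen in the same way. With PrlR+/+ 2, PrlR+/- 3 and PrlR+/- 4 apart, the shares were 14.9% of unnamed probe sets and 11.5% of genes. No batch was known, and no biological explanation was tested.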
